A study of Mus musculus with 2 samples.

How the data were processed

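MicroRNA sequencing was performed by the study on total RNA from the adrenal gland of B6CASTF1/J mice, a first-generation hybrid strain, at 2 months of age. The labels gave 1 group, female adrenal gland, with 2 biological replicates whose tissue labels number different females. Both samples carry the same donor label, so their separation into 2 animals rests on the tissue labels and the replicate numbers alone, and otherwise the SDs measure the spread between samples only. They named no treatment and no second group, so the design held no contrast between conditions. The comparisons were the abundance of miRNA genes within the tissue and the spread between the 2 replicates.

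The values were read counts per miRNA gene as deposited, not normalized, in a table per sample. Per the sample information deposited with the counts, the assembly was mm10 and the annotation GENCODE M21. The aligner and the counter and their versions were not given in the sources used here. Each deposited table held 4 columns, the gene identifier and the counts taken without regard to strand, on the gene's strand, and on the opposite strand. It began with 4 rows that name no gene: unmapped reads, reads aligned to several places, reads outside the counted genes and reads that fell in more than 1 gene. These rows were kept out of library sizes and tests. With the strand of the gene, they held 29.8%, 28.8%, 10.8% and 8.62e-05% of the 9278190 reads of replicate 1. In replicate 2 they held 39.7%, 25.3%, 8.60% and 0% of 8659511 reads. The tables held 2202 genes, all of which were matched by identifier to the 2207 miRNA genes of GENCODE M21, which gave symbols, coordinates (mm10, counted from 1) and the transcripts that overlap each gene on its strand. Counting was per hairpin gene, so the 2 arms of a hairpin could not be told apart. Reads aligned to several places were not assigned to a gene, so a gene whose mature miRNA is also made by another gene kept only the reads that differ. Genes with a stretch of 20 bases in common with another annotated hairpin were marked as such. Neither allele-specific reads nor variants of the hybrid strain against the reference were analysed here.

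The column on the strand of the gene was the main measure, as the single-strand column with the larger total. Counts were scaled to a total of 1000000 over the genes of each library (CPM). Means are given with the standard deviation (SD) over the 2 replicates. A gene was called detected at 10 or more counts in both libraries. Agreement was measured by Pearson's r and Spearman's rho across genes of log2(CPM + 1) over genes with a mean count of at least 10. The biological coefficient of variation (BCV), the square root of the common dispersion, was estimated with edgeR 4.0.16 with an intercept only and TMM scaling. Each gene was compared between the libraries by an exact two-sided binomial test on the counts given the totals, with Benjamini-Hochberg adjustment, and passed at an adjusted p under 0.05 and a difference of at least 2-fold. That test compares these 2 libraries and covers counting error only. With 2 samples the smallest exact two-sided p over samples is 0.5, so no exact test over samples could pass, and none was run.

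Before the data were examined, 20 gene lists were fixed from textbook knowledge. They were the let-7 family, miRNAs described in adrenal cortex or steroidogenic cells, neuroendocrine and neuronal, endothelial, smooth muscle and fibroblast, blood cell, skeletal and heart muscle, liver, kidney and gut epithelium and fat miRNAs. They also included the Dlk1-Dio3 imprinted region, the Sfmbt2 intronic cluster, the X-linked cluster near Fmr1, miR-17-92 with its paralogous clusters, the miR-30, miR-10/99/100, miR-26/29 and miR-181 families, hypoxia and stress miRNAs, and genes whose mature miRNA is shared with another gene. For each list the share of counts was computed per sample. For lists with at least 5 tested members the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression. The genes named were the 20 of highest mean CPM, up to 4 of the most abundant detected members of each list, and the 5 genes with the largest ratio in each direction with a mean count of at least 100, by a rule fixed at the same time. Other list members that passed the test, and members of neighbouring clusters, were named after their values were seen.

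Ratios carry exact 95% intervals and list shares Clopper-Pearson 95% intervals. The libraries carry no stated molecular identifiers, so these and the detection floors cover counting error only. A count was worth 0.352 CPM in replicate 1 and 0.439 CPM in replicate 2. A count of 0 allows up to 3 counts, or 1.06 and 1.32 CPM.

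The procedures were tested on simulated data. Over the 369 genes of the comparison of replicate 2 with replicate 1, the binomial rule recovered 99 of 100 genes simulated at 4-fold and 4 of 100 at 1.5-fold, and called 1 of the genes left unchanged. These counts were simulated with counting error only (Poisson), so the result does not show how often the rule calls genes between samples that vary. A simulated BCV of 0.3 was estimated as 0.298.

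The alternatives were counts without regard to strand, count minimums of 1 and 50, no filter and a filter at a mean count of 100, a pseudocount of 10 CPM, TMM and median-of-ratios scaling (DESeq2 1.42.0), an edgeR exact test with an assumed BCV of 0.2, leaving out each replicate, and list shares without the most abundant gene or without genes that share a mature miRNA. Leaving out the muscle and blood cell lists, and recomputing list percentiles from unstranded counts or at a mean count of 100, were added after the data were seen. Computation used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.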

Results

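MicroRNAs of the adrenal gland were profiled in 2 samples from female B6CASTF1/J mice at 2 months of age, which the tissue labels number as different animals. The adrenal gland consists of a steroid-producing cortex and a catecholamine-producing medulla. Gene counts on the sense strand totalled 2839732 in replicate 1 and 2280028 in replicate 2, which was 30.6% and 26.3% of the reads of each library. Values are means ± SD with n = 2 unless stated otherwise, and positions are in mm10.

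The first question was which miRNA genes make up the adrenal profile. The let-7 family, regulators of cell differentiation, held 32.4% ± 0.708 of all gene counts (32.9% and 31.9%), and all 12 of its members in the tables were detected. Shares and ranks cover assigned reads only. Reads aligned to several places, 94.2 and 96.2 per 100 gene counts in replicates 1 and 2, were not assigned. Among let-7 genes, 6 share a stretch with another hairpin and may have lost reads in this way, so the order of let-7 genes holds for assigned reads. Mirlet7b was the most abundant gene in both libraries, at 133714 ± 12170 CPM, followed by Mirlet7g at 87939 ± 9209 CPM, and each exceeded the next gene in both libraries by more than the SDs. Mir378a, which lies in the metabolic coactivator gene Ppargc1b, reached 52753 ± 5554 CPM, and Mir126a, an endothelial miRNA within Egfl7, reached 51333 ± 11498 CPM. Mir375, known from neuroendocrine cells and pancreatic islets, was present at 38600.4 ± 1160 CPM.

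Mirlet7b (ENSMUSG00000065564.1) lies on chromosome 15 from 85707319 to 85707403 on the plus strand, in an exon of the noncoding transcript Lncppara, and its 85-base hairpin reads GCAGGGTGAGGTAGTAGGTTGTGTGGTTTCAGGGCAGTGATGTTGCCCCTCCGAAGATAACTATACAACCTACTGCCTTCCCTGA. Mirlet7g lies in an intron of Wdr82 on chromosome 9 (106178840 to 106178927). Mir378a occupies chromosome 18 from 61397835 to 61397900 on the minus strand. Mir126a occupies chromosome 2 from 26591357 to 26591429, in sequence that is exonic in an Egfl7 transcript. Mir375 (chromosome 1, 74900658 to 74900721, minus strand) overlaps no annotated transcript on its strand, and its 64-base hairpin reads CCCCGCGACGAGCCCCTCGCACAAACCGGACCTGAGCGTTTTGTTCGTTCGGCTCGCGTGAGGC.

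Among the other abundant genes, Mirlet7i (41516 ± 208 CPM), Mir10b (13981 ± 106 CPM) and Mir744 (11611 ± 79.6 CPM) differed little between the replicates. Mir139 in Pde2a reached 40019.6 ± 4612 CPM, Mirlet7d 37259 ± 6276 CPM and Mir10a 36323 ± 3588 CPM, and these 3 could not be ranked against Mir375 beyond their SDs. Mir23b (29891 ± 4629 CPM) and Mir23a (26138 ± 4879 CPM) exchanged their order between the libraries. Mir143 reached 22074 ± 1463 CPM, Mir26b 15797 ± 3251 CPM, Mir652 15114 ± 3985 CPM and Mirlet7e 11532 ± 1870 CPM. In contrast, Mir22 was at 50215 CPM in replicate 1 and 12041 CPM in replicate 2, and Mir21a at 33612 and 13012 CPM. Mir127, a maternally expressed gene of the Dlk1-Dio3 region, was at 13998 and 24356 CPM.

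Of 2202 miRNA genes, 342 were detected in both libraries and 1463 had no count in either. The 10 most abundant genes held 55.1% ± 1.52 of the counts, 9 genes held 50% and 50 genes held 90%. A total of 74 genes exceeded 1000 CPM in both libraries and 21 exceeded 10000 CPM.

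**Figure D1:**
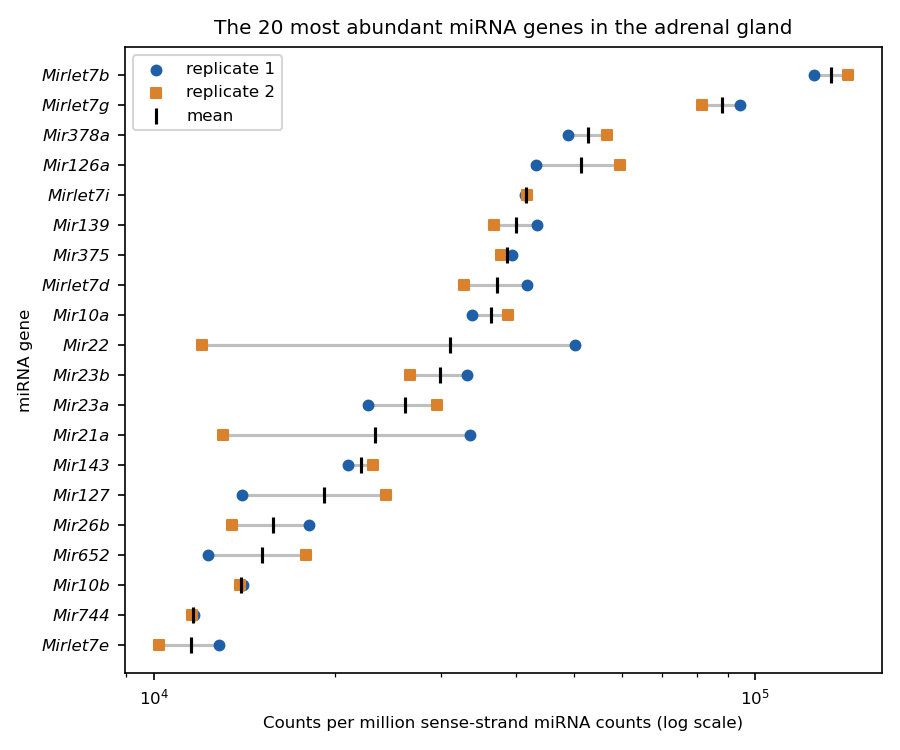
CPM of the 20 miRNA genes with the highest mean in adrenal gland, with a point for each replicate, a line that joins them and a tick at the mean (n = 2). Mirlet7b lies highest at 133714 CPM, and the points of Mir22 and Mir21a lie far apart.

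The next comparison concerned the gene lists named after cell types or states of the gland and its surroundings. Their shares do not measure cell types, since single genes made up most of several lists. Mir21a, for example, made up 51.0% of the steroidogenic list and 86.0% of the hypoxia and stress list. Mir21a, Mir34a, Mir132 and Mir212 belong to both of these lists. miRNAs described in adrenal cortex or steroidogenic cells held 4.57% ± 1.53 of the counts and all 17 were detected, led by Mir21a, with Mir320 at 6301 ± 2064 CPM, Mir125a at 5770.1 ± 3436 CPM and Mir455 at 2712 ± 265 CPM. Neuroendocrine and neuronal miRNAs held 4.33% ± 0.198, with 16 of 23 members detected, and Mir375 alone made up 89.1% of the list. Mir7b (2623 ± 675 CPM), Mir182 (798 ± 111 CPM) and Mir183 (448 ± 111 CPM) followed. Endothelial miRNAs held 5.13% ± 1.15, nearly all from Mir126a, and smooth muscle and fibroblast miRNAs 2.44% ± 0.166, led by Mir143 with Mir145a (1209 ± 118 CPM) and Mir214 (1055 ± 78.6 CPM).

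The fat list held 5.44% ± 0.590, of which Mir378a made up 97.1%, while Mir193a was at 842 ± 75.1 CPM, Mir193b at 537 ± 255 CPM and Mir196a-2 at 164 ± 1.63 CPM. Kidney and gut epithelium miRNAs held 3.74% ± 0.310 with 8 of 14 members detected. Mir10a made up 97.1% of that list, and Mir203 (860 ± 433 CPM), Mir194-2 (38.9 ± 2.27 CPM) and Mir204 (37.1 ± 7.24 CPM) were far lower. The liver miRNA Mir122 was at 3721 CPM in replicate 1 and 2358 CPM in replicate 2, rank 46 of all genes. Hypoxia and stress miRNAs held 3.70% in replicate 1 and 1.72% in replicate 2, with Mir21a, Mir34a (2542 ± 1135 CPM), Mir132 (991 ± 586 CPM) and Mir210 (222 ± 61.4 CPM).

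Blood cell miRNAs held 0.197% of the counts in replicate 1 (95% interval 0.192 to 0.203) and 1.55% in replicate 2 (1.54 to 1.57). Skeletal and heart muscle miRNAs held 0.0953% in replicate 1 (0.0918 to 0.0990) and 0.000658% in replicate 2 (0.000368 to 0.00109), and none of their 10 members was detected in both. In these 2 lists, and in the X-linked cluster near Fmr1 (0.00173% and 0.000395%), the difference between the replicates was larger than the mean.

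**Figure D2:**
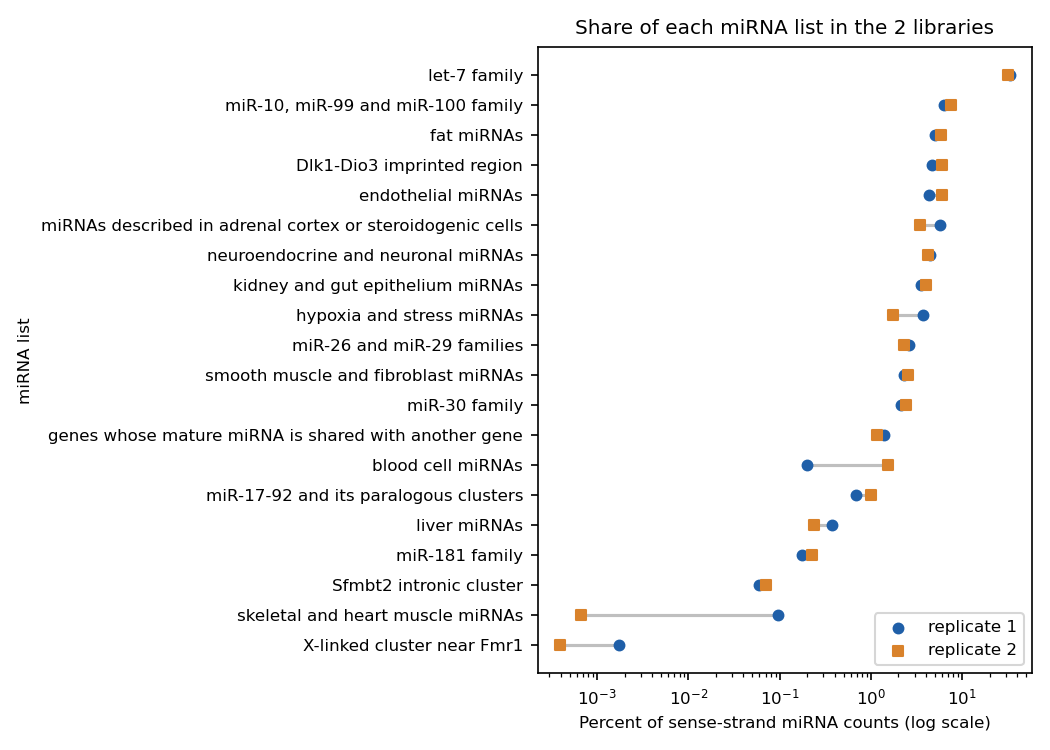
Share of miRNA gene counts, on a log axis in percent, held by each of the 20 gene lists, with a point for each replicate. The points of most lists nearly coincide, while muscle miRNAs (0.0953% and 0.000658%), blood cell miRNAs (0.197% and 1.55%) and the X-linked cluster near Fmr1 (0.00173% and 0.000395%) lie apart.

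Genomic clusters and miRNA families were compared within the tissue. The Dlk1-Dio3 imprinted region, whose miRNAs are expressed from the maternal chromosome, held 5.32% ± 0.951 of the counts, and 49 of its 57 members were detected. Mir127 made up 36.0% of the region, and Mir379 (5130.5 ± 323 CPM), Mir541 (4719 ± 1690 CPM) and Mir411 (4371 ± 156 CPM) came next, with an order that differed between the libraries. By comparison, the Sfmbt2 intronic cluster held 0.0652% ± 0.00858, with 6 of 54 members detected, led by Mir467d (348 ± 74.9 CPM), Mir669c (115 ± 12.8 CPM), Mir467e (99.1 ± 3.72 CPM) and Mir669o (45.3 ± 5.15 CPM). Members of that cluster share long stretches with each other, so their values are uncertain. No member of the X-linked cluster near Fmr1, known from testis, was detected in both libraries, and its 22 members held 49 counts in replicate 1 and 9 in replicate 2.

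The miR-10/99/100 family held 6.91% ± 0.816, with Mir10a, Mir10b, Mir99a (10929 ± 448 CPM) and Mir99b (6248 ± 4305 CPM). The miR-26/29 families held 2.46% ± 0.254, led by Mir26b, Mir29a (7276 ± 954 CPM) and Mir29c (1208 ± 86.7 CPM). Mir26a-1 and Mir26a-2 share a mature miRNA and kept only the reads that differ, so Mir26b leads among assigned reads only. The miR-30 family held 2.28% ± 0.208, led by Mir30d (10071 ± 1324 CPM), which exceeded Mir30a (7077 ± 117 CPM) in both libraries by more than the SDs, as Mir30a did Mir30e (4760.3 ± 653 CPM). miR-17-92 and its paralogs held 0.846% ± 0.226, with Mir93 (2807 ± 1069 CPM), Mir17 (2282 ± 780 CPM), Mir92-1 (1362 ± 233 CPM) and Mir106b (803 ± 8.71 CPM). The miR-181 family held 0.175% in replicate 1 and 0.224% in replicate 2, with Mir181d (759 ± 267 CPM), Mir181c (689.8 ± 42.0 CPM), Mir181b-2 (472 ± 124 CPM) and Mir181a-1 (52.4 ± 11.5 CPM). In this family 4 members, among them Mir181b-2 and Mir181a-1, share a stretch with another hairpin and may have lost reads. The share and the order of the miR-181 genes therefore hold for assigned reads only. Genes whose mature miRNA is shared with another gene held 1.28% ± 0.152, led by Mirlet7f-2 (3918 ± 1415 CPM), Mirlet7c-2 (1907 ± 296 CPM), Mir92-1 and Mir16-1 (923 ± 253 CPM), and their reads aligned to several places are not in these counts.

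The last comparison was between the 2 replicates. Muscle miRNAs were nearly restricted to replicate 1: Mir206, a skeletal muscle miRNA, had 1517 counts there and 5 in replicate 2, Mir499, from the myosin gene Myh7b, had 818 and 4, and Mir208b, from the myosin gene Myh7, had 354 and 1. Their CPM was higher in replicate 1 by 244-fold (95% interval 104 to 751), 164-fold (63.9 to 604) and 284-fold (50.7 to 11258). The erythroid miRNAs Mir451a and Mir144 were higher in replicate 2, Mir451a with 1333 counts against 30910 (28.9-fold, 27.3 to 30.5) and Mir144 with 305 against 1990 (8.13-fold, 7.20 to 9.20). Mir486, also erythroid and named after its values were seen, had 187 and 133 counts, a ratio of replicate 2 to replicate 1 of 0.886 (0.704 to 1.11). Its hairpin shares stretches with another, so reads may be missing from its counts, and any effect on the ratio was not tested. Mir185, in an intron of Tango2, was 8.79-fold higher in replicate 2 (386 against 2725 counts).

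Other genes with large ratios were Mir26a-2 (1253 against 35 counts) and the myeloid miRNA Mir223 (377 against 40), both higher in replicate 1, and Mir99b (2.90-fold) and Mir331 (2.85-fold), both higher in replicate 2. Mir26a-2 shares its mature miRNA with Mir26a-1, so its counts hold only the reads that differ and do not give a ratio of the mature miRNA. The white cell miRNAs Mir142 (ratio of replicate 2 to replicate 1 of 1.02), Mir155 (1.07) and Mir150 (0.708) did not pass the 2-fold rule. Mir206 lies on chromosome 1 from 20679010 to 20679082 in an exon of the noncoding gene Gm28653, with the hairpin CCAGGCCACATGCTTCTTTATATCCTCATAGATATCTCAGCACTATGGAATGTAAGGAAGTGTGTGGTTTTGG. Mir451a (chromosome 11, 78073170 to 78073241) and Mir144 (78073005 to 78073070) are neighbours on the plus strand and overlap no other annotated transcript on that strand. The Mir451a hairpin reads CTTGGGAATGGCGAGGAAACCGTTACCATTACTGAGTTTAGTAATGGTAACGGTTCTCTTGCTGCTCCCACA.

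Across 369 genes, log2(CPM + 1) correlated between the replicates with r = 0.955 and rho = 0.948, where genes are not independent replicates. The median size of the log2 difference was 0.43, and 81.0% of the genes differed by less than 2-fold. The BCV was 44.8%, and 35.7% without the muscle and blood cell lists, a setting added after the data were seen. By the exact binomial test 231 genes had an adjusted p under 0.05, and 69 of them differed by at least 2-fold, 32 higher in replicate 2 and 37 higher in replicate 1. With median-of-ratios scaling 24 were higher in replicate 2 and 45 in replicate 1. At a mean count of at least 100, 33 of the 234 genes tested passed. The chi-square statistic over these genes was 203204 on 368 degrees of freedom, so the tables do not hold a single library deposited in duplicate. That they are 2 samples rests on the labels.

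By list, 3 of 3 tested muscle miRNAs passed as higher in replicate 1, and among the 7 tested blood cell miRNAs Mir451a and Mir144 passed as higher in replicate 2 and Mir223 as higher in replicate 1. Of 17 adrenal cortex or steroidogenic miRNAs, 5 were higher in replicate 1 (Mir21a, Mir125a, Mir132, Mir24-2 and Mir483) and 12 did not pass. Mir24-2 shares its mature miRNA with Mir24-1, and Mir483 rests on 63 against 25 counts. Of 12 tested kidney and gut miRNAs, 4 were higher in replicate 1: Mir203 and the neighbouring hairpins Mir200b (99 against 8 counts), Mir200a (19 against 4) and Mir429 (37 against 5). The other 8 did not pass, among them Mir141 and Mir200c (log2 ratios -0.03 and -0.20). In the Dlk1-Dio3 region 5 of 49 were higher in replicate 1 (Mir487b, Mir299a, Mir323, Mir380 and Mir410). Of the neuroendocrine list Mir153 was higher in replicate 2 and Mir128-1 in replicate 1, and 14 did not pass. Mir193b and Mir365-1 of the fat list, Mir99b of its family and Mir181b-1 were higher in replicate 2. Mir26a-2 and Mir26a-1, Mir21a and Mir132 of the hypoxia and stress list, Mir669l of the Sfmbt2 cluster, and Mir547 and Mir201 of the X-linked cluster were higher in replicate 1. Mir26a-2, Mir26a-1, Mir24-2, Mir128-1, Mir365-1 and Mir181b-1 each share a mature miRNA with another gene. Their counts hold only the reads that differ and do not give a ratio of the mature miRNA. Of the genes with a shared mature miRNA, 3 were higher in replicate 2 and 4 in replicate 1. No member of the let-7, smooth muscle, miR-17-92 or miR-30 lists, nor Mir126a or Mir122, passed. When adjusted over the list alone, the number of members that passed was the same in all 20 lists.

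Set against random lists matched on expression, the median log2 ratio of replicate 2 over replicate 1 lay at percentile 1.01 for the adrenal cortex or steroidogenic list (median -0.33) and at percentile 0.900 for the neuroendocrine list (median -0.39), as a description of these libraries. The median weighs all members alike. Mir375, 89.1% of the neuroendocrine list, had a ratio of 0.958, and that list held 4.47% of the counts in replicate 1 and 4.19% in replicate 2. The muscle miRNAs were higher in the same library as both lists. These 2 of 16 lists lay outside the middle 95% of random lists, and at a mean count of at least 100 they lay at percentiles 4.19 and 6.84, inside it. With unstranded counts they lay at percentiles 2.55, just inside it, and 0.160, outside it. Both settings were added after the data were seen. Random lists drew genes singly, so the percentiles do not allow for like ratios of neighbouring genes. The let-7 list lay at percentile 3.75, kidney and gut at 4.47, hypoxia and stress at 4.15, miR-26/29 at 5.13, shared mature miRNAs at 3.44 and Dlk1-Dio3 at 48.5. The remaining lists lay at 40.3 (blood), 44.5 (miR-10/99/100), 56.1 (Sfmbt2), 56.3 (smooth muscle), 70.8 (miR-181), 76.2 (fat), 77.4 (miR-30) and 83.015 (miR-17-92).

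**Figure D3:**
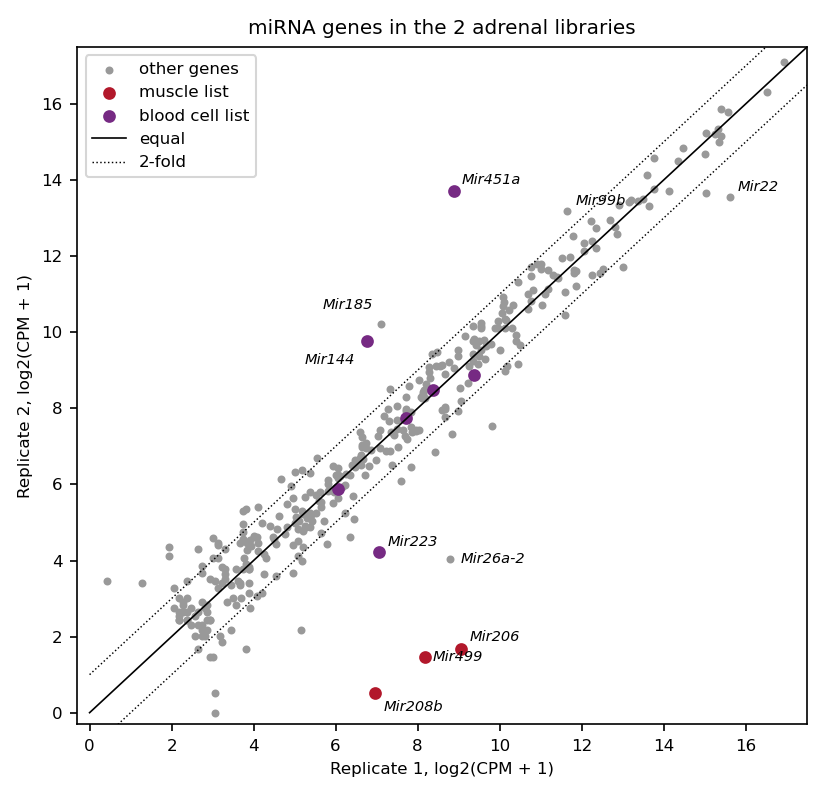
CPM of each miRNA gene in replicate 2 against replicate 1 on log axes, over the 369 genes compared (r = 0.955 on log2(CPM + 1)). Most genes lie near the diagonal, with Mir206, Mir499 and Mir208b far to the replicate 1 side and Mir451a far to the replicate 2 side.

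Strand was also compared, since it decides which genes keep their reads. Sense counts made up 89.1% and 86.5% of the stranded counts. Genes with a mean count of at least 1000 were picked if they kept at most 1% of their sense counts in the unstranded counts. These were Mir378a, Mir126a, Mirlet7e, Mir451a, Mir191, Mir30e, Mir337, Mir409 and Mir497, and each overlaps an annotated miRNA gene on the other strand. These 9 genes held 11.98% and 15.4% of the sense counts. Of all genes, 64 overlap a miRNA gene on the other strand, and the loss over that whole group is not given here. Mir126a, for example, had 122684 and 135577 sense counts but 5 and 8 unstranded counts. Genes with fewer counts were affected too, such as Mir142, with 595 and 486 sense counts and 0 unstranded counts.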

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

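The tests of counting error, muscle RNA, white blood cells, GC content and primary transcripts were chosen after the ratios between the libraries had been seen. With 2 samples in 1 group, no sample could be tested as lying far from the others. The design gives no second group, so no difference between conditions was tested.

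Signals outside the main measurement stood above what a count of 0 allows. Antisense counts with no miRNA gene on the other strand to account for them came to 237 in replicate 1 and 150 in replicate 2, of which Mir203 held 147 and 75. Reads aligned to several places numbered 2673681 in replicate 1 and 2193599 in replicate 2, or 94.2 and 96.2 per 100 gene counts. Reads aligned outside the miRNA genes numbered 1000436 and 744833.

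Markers of other tissues differed between the libraries, with the muscle miRNAs Mir206, Mir499 and Mir208b almost only in replicate 1 and the erythroid miRNAs Mir451a and Mir144 higher in replicate 2. Counting error is argued against, since the exact interval of the ratio excluded 1 for 4 of 4 countable muscle genes and lay above 1 for 2 of 2 erythroid genes, and a larger share of white blood cells as well as red cells in replicate 2 is argued against by 0 of 4 white cell genes (Mir142, Mir150, Mir155 and Mir223) with an interval above 1. Mir486, a further red cell gene, was not higher in replicate 2 (187 against 133 counts). Reads of its shared stretch may be missing, and any effect on its ratio was not tested. Muscle RNA in the replicate 1 sample stays open for the first part: 4 of 4 countable members were higher there, which restates the pattern and lends no further support, with Mir206 at 534 CPM, Mir499 at 288 CPM, Mir208b at 125 CPM and Mir208a with 13 counts against 0. The abundant muscle miRNAs Mir1a-1, Mir1a-2 and the Mir133 genes could not be checked, since they share mature sequences and held 0 to 2 counts; muscle adhering at dissection, red cells left in the tissue, reads from another library and a difference between the animals remain open and were not separated here.

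Across genes, the spread of log2 ratios between the libraries had several candidate sources. GC content of the hairpin had a rho of 0.135 with the ratio across 369 genes. By the bounds set, that value was too small to call and too large to dismiss. A linear fit on GC was added after rho was known, so it adds little to rho. It took up 1.19% of the variance, which argues against a linear trend with hairpin GC as the main source. GC of the sequenced arm could not be tested, since counts were per hairpin. Primary transcripts that differ between the samples are a candidate source, since neighbouring hairpins within 10 kb on one strand had like ratios, with an intraclass correlation of 0.497 over 47 clusters and 161 genes (permutation p = 0.0001, the smallest that 10000 shuffles can give) and 0.361 without the muscle and blood cell lists. Mir200b, Mir200a and Mir429 shared a direction (log2 ratios -3.31, -1.93 and -2.57), whereas Mir99b, Mirlet7e and Mir125a in Spaca6 moved apart (1.54, -0.33 and -1.30). Tissue makeup and a difference between the animals remain open.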

How the results depend on the processing

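No paired analysis was possible because the design held 1 group. Settings without the muscle and blood cell lists and both settings of list percentiles were chosen after seeing the data. Detected genes rose to 555 at a minimum of 1 count. Unstranded counts gave the top 10 genes 58.3% of counts. They changed list shares to 36.3% (let-7), 5.02% (neuroendocrine), 0.000308% (endothelial), 2.83% (smooth muscle), 4.36% (kidney and gut), 0.187% (fat), 0.171% (blood cell, from 0.876%), 0.0758% (Sfmbt2), 8.04% (miR-10/99/100) and 2.85% (miR-26/29), since genes overlapped on the other strand, such as Mir126a, Mir378a and Mir451a, lose their reads and the total falls. Without Mirlet7b, the most abundant gene, shares were 21.997% (let-7), 5.00% (neuroendocrine), 2.81% (smooth muscle), 4.32% (kidney and gut), 6.28% (fat), 0.0753% (Sfmbt2), 2.64% (miR-30), 7.98% (miR-10/99/100), 2.84% (miR-26/29) and 1.47% (shared mature), by the smaller total. The miR-181 share was 0.147% without genes that share a mature miRNA. The r between replicates was 0.974 without a filter, 0.921 at a mean count of 100, 0.967 with a pseudocount of 10 CPM and 0.974 without the muscle and blood cell lists, and the BCV was then 35.7%. Genes that differed numbered 33 of 234 tested at a mean count of 100, against 69 of 369 in the main setting. With an assumed BCV of 0.2 they numbered 35 of 369 (12 higher in replicate 2, 23 in replicate 1). Under the other settings they numbered 59 to 76. The percentile of the steroidogenic list was 2.55 with unstranded counts and 4.19 at a mean count of 100, and that of the neuroendocrine list 6.84 at a mean count of 100, inside the middle 95%; fewer genes were tested there. Median-of-ratios scaling moved every log2 ratio by -0.16, so the list medians of smooth muscle, blood, Dlk1-Dio3, Sfmbt2 and miR-10/99/100, close to 0, changed sign. Of 76 named genes, 37 moved in CPM by more than the SD with unstranded counts. With 2 replicates, leaving out either cannot move a mean by more than the SD and tests no stability: Mir451a was then 469 or 13557 CPM and Mir206 2.19 or 534 CPM. Low counts limit genes near 10 counts, such as Mir208a.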

Other observations

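The Mir290 to Mir295 and Mir302/Mir367 clusters, known from embryonic stem cells and chosen here after the data were seen, had low counts in both libraries. Their 14 genes held 309 counts in replicate 1 and 258 in replicate 2, or 109 and 113 CPM, and 6 were detected in both. Mir294 had 75 and 57 counts, Mir292 60 and 54, Mir302d 43 and 54, Mir293 53 and 36, Mir302b 33 and 21 and Mir302a 31 and 14, while Mir367 had none in either library. Whether these reads came from the tissue or from other libraries was not tested. Mir302b and Mir302a each share a 20-base stretch with another hairpin.

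Genes with a shared mature miRNA held few counts, and the test of this was chosen after the result was seen. Reads that align to several genes were not assigned by the counting rule, so such reads are missing from these counts. How much of the low counts this loss accounts for stays open. In 5 of 5 families the members with a shared stretch had the lower median CPM. Examples were 623 against 39387 CPM in the let-7 family, 373 against 5919 CPM in miR-30 and 37.2 against 11536 CPM in miR-26/29. The counting rule itself favours this order, so the order does not measure the size of the loss. Lower transcription of these genes would give the same order. Its part cannot be told apart from the loss here, since the reads aligned to several places are not given per gene.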
